A study of Mus musculus with 28 samples.

How the data were processed

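Total RNA from mouse prostate or prostate tumours was amplified, labelled and hybridised to Illumina mouse bead arrays, per the labels' protocols. The samples were 28 arrays in 6 groups on 7 slides. NPK denotes mice in which an inducible Cre under the Nkx3-1 promoter deletes floxed Pten and switches on a mutant Kras allele in prostate cells. RAPPD denotes rapamycin, an mTOR inhibitor, given with PD0325901, a MEK inhibitor, a reading taken from background knowledge of the study and not from the labels. Docetaxel is a taxane that stabilises microtubules. Groups came from the labels for genotype, treatment and duration. The duration labels read LONG and SHORT, and the protocol states 5 daily treatments with harvest on the fifth day for every sample, so what LONG and SHORT stand for is not given in the sources used here. Slides came from the sample titles. Wild-type arrays filled slide 1, RAPPD LONG arrays 1 to 3 filled slide 2, slide 3 held RAPPD LONG array 4 with vehicle LONG arrays 1 and 2, and slide 4 held RAPPD LONG array 5 with vehicle LONG arrays 3 to 5. Docetaxel, vehicle SHORT and RAPPD SHORT filled slides 5, 6 and 7. For these SHORT groups and for wild type, slide and group cannot be told apart. The labels give no replicate numbers, so replicates were numbered in the order of the sample list, and the numbers were not used to pair arrays across groups.

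The authors deposited a table of bead intensity values, named as not normalized, and a table of processed values on a log2-like scale. The submitters' processing notes name BeadStudio and lumi without versions and without saying which step each did. The deposited intensity table held no detection p-values. Its values were background-subtracted, with 33.0% to 42.7% of the 45281 probes below 0 on an array, and had similar means on all arrays, 643 to 685 intensity units. Whether arrays were scaled to each other before deposit is not given in the sources used here. The deposited log2 values followed the intensities of the same array along 1 smooth curve, with a rank correlation of at least 0.999922 and medians of 7.57 to 7.64, so they are a transform of those intensities without centring of genes. How that transform was set is not given in the sources used here.

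Levels were computed from the intensities with the normexp background correction of limma with an offset of 50, which keeps negative values usable, then quantile normalization and log2. Probes were kept when their mean over all arrays exceeded the 40th percentile of all probes. Gene names came from the platform annotation supplied with the values. Of the probes, 34885 had 1 symbol, 18 had several and 10378 had none. Probes with 1 symbol covered 19057 symbols. Of these probes, 34807 matched a gene of the RefSeq table, and no symbol was changed by the match. A gene was represented by its probe with the highest mean, which left 13816 genes. A further 4859 kept probes without a single symbol were tested and counted but not named. Pten, Kras, Nkx3-1, Mki67 and Ccnb1 had no named probe and are not analysed here. A probe was called above background on an array when its intensity exceeded 3 times the noise, which was estimated from that array's negative values. Between 33.1% and 47.5% of probes were above background on an array. Where a gene was above background on no array of a group, its level there is only a limit. The fold is then given as at least the brighter group's mean over the dim group's mean of, per array, the higher of the gene's own value and the lowest value among probes above background. The files mark no saturated probes. Tgm4 on wild-type arrays and Wfdc2 on vehicle LONG arrays reached 86% to 93.6% and 86.2% to 92.6% of the brightest probe of the array, and Svs3b on RAPPD SHORT arrays 52.6% to 100%, so their changes may be understated too. The number of arrays limits the precision of every value.

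Each comparison was a contrast in a single limma fit with 1 mean per group over all arrays, with 22 residual and 3.48 prior degrees of freedom, tested by eBayes with Benjamini-Hochberg adjustment at 0.05 over the genes. The labels do not say that arrays came from separate mice, so p-values measure only the spread between these arrays, which may be partly technical. The comparisons were NPK vehicle LONG with wild type, each treatment with the vehicle of its arm, RAPPD SHORT with docetaxel, vehicle SHORT with vehicle LONG, and the difference of the RAPPD effect between arms. Gene lists, the rule for named genes and all alternatives except those said to be added later were fixed before the data were examined. The 31 lists cover signalling and metabolic programs, the cell cycle, and markers of cell types that a prostate sample can hold. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, and fry was run as an alternative. Counts of members used adjustment over all genes and also adjustment over the list alone. Named genes were the 8 largest rises and 8 largest falls among genes past the threshold (clone and predicted names left out), up to 4 members of each list with the smallest p, and in treatment comparisons a fixed set of readouts of MEK signalling and proliferation.

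Overlaps between comparisons were set beside the product of their call counts over the genes tested, per direction. Where comparisons shared vehicle arrays, unchanged groups were simulated 50 times against those arrays, and the vehicle arrays were split between the comparisons 20 times. Alternatives to the main processing were no background correction, an offset of 16, median scaling, cyclic loess, the deposited log2 values, no filter, a filter at the 60th percentile, the mean of all probes of a gene, only the groups compared, eBayes with trend and robust settings, array weights, slide as a random or fixed block where it holds more than 1 group, comparison within slides, a threshold of 1 on the log2 change, and leaving out each array in turn. Array position, the arrays at positions D and E of the SHORT slides, vehicle arrays 4 and 5 of each arm, the closest pair of arrays in each NPK group averaged and the seminal vesicle list as a covariate were added after seeing the data. The closest pairs were arrays 4 and 5 of vehicle LONG, vehicle SHORT and docetaxel, and arrays 2 and 3 of RAPPD LONG and RAPPD SHORT.

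The gene test was checked on simulated data built from each gene's own mean and spread, with 13816 genes. For RAPPD SHORT against vehicle it recovered 14.9%, 70.1% and 93.9% of genes changed by 0.5, 1 and 2 log2 units, with 10 false calls. For the comparison of NPK with wild type it recovered 10.4%, 50.7% and 92.4%, with 2 false calls. A shift of -1 in the MAPK/ERK output list was found in both, with 0 and 1 other lists called. The simulated genes varied independently of each other, so this check cannot show how the list test behaves where genes of a list are correlated. Software was R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.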

Results

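Expression was profiled on 28 bead arrays of mouse prostate and prostate tumour RNA. Wild-type prostate (C57Bl/6J, vehicle, LONG) had n = 3 arrays, and each group of NPK mice had n = 5, namely vehicle LONG, RAPPD LONG, vehicle SHORT, RAPPD SHORT and docetaxel SHORT. Mean signal per array lay between 643 and 685 intensity units and the median between 14.0 and 25.5, with 33.1% to 47.5% of 45281 probes above background. Changes are log2 differences with their standard error (SE) and the limma p-value adjusted over 13816 genes. The title of the series names the prediction of drug response in prostate cancer from mouse models as its purpose. Wild type, vehicle SHORT, RAPPD SHORT and docetaxel SHORT each filled a slide alone, so slide and group cannot be told apart for them, and every comparison with 1 of these groups also compares slides.

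NPK vehicle LONG tumours (n = 5) were compared with wild-type prostate (n = 3). Several genes of prostate secretion were far lower in the tumours. Tgm4, the prostate transglutaminase, fell by 7.98 (SE 1.49, adjusted p = 9.26e-05) and was above background on 1 of 5 tumour arrays. No tumour array was above background for Pbsn, the androgen-driven probasin, which was at least 28.4-fold lower (adjusted p = 9.7e-16). The same held for Pnliprp1, at least 144-fold lower (adjusted p = 1.78e-09), and Spink8, at least 101-fold lower (adjusted p = 8.81e-05). Msmb fell by 4.83 (SE 0.85) and the lipid-mobilising Azgp1 by 6.04 (SE 0.60). Of 11 measured members of the prostate secretory luminal list 6 fell and 1 rose, the keratin Krt8 (1.09, SE 0.18). The list itself did not pass (adjusted p = 0.0959). Ltf, which encodes the iron-binding lactotransferrin, rose by 8.57 (SE 0.26, adjusted p = 2.13e-18). Its intensity was 85.7% to 100% of that of the brightest probe on the vehicle LONG arrays, so the rise may be understated if the probe was saturated, which the files do not mark. Wfdc18 was at least 92.9-fold higher (adjusted p = 3.38e-14) and the mucosal chemokine Cxcl17 at least 101-fold (adjusted p = 5.81e-13). Other secreted proteins that rose were the surfactant protein Sftpd (at least 57.3-fold, adjusted p = 2.13e-11) and the lectin Reg3b (at least 41.3-fold, adjusted p = 8.45e-05).

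Markers of other epithelial states were higher in the tumours. Of 9 proximal luminal genes 7 rose and 1 fell (adjusted p = 1.52e-06, and adjusted p = 0.0197 with an estimated correlation), led by Ly6d at 6.54 (SE 0.28), Wfdc2 at 6.40 (SE 0.25) and the keratin Krt7 at 4.72 (SE 0.18). Of 10 basal genes 7 rose (adjusted p = 0.000123, adjusted p = 0.381 with an estimated correlation), among them Krt17 at 4.52 (SE 0.32) and the hemidesmosome integrin Itgb4 at 3.49 (SE 0.16). The MAPK/ERK output list, made of genes switched on downstream of MEK, had 10 of 17 members up (adjusted p = 0.0016, adjusted p = 0.381 with an estimated correlation), with Phlda1 at 4.15 (SE 0.27), Ier3 at 3.37 (SE 0.30) and the ERK phosphatase Dusp4 at 2.94 (SE 0.39). In the p53 target list 11 of 19 rose and 2 fell (adjusted p = 0.0124, adjusted p = 0.381 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 3.37 (SE 0.29). Counts adjusted over the list alone were the same for these 4 lists.

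Of the lists of immune and stromal cells, 7 were also higher in the tumours, while the T and NK cell (adjusted p = 0.73) and B and plasma cell lists (adjusted p = 0.148) did not pass. Interferon response genes rose in 12 of 16 cases (adjusted p = 2.14e-06, adjusted p = 0.381 with an estimated correlation), with the antiviral Ifit3 at 5.41 (SE 0.42) and the transcription factor Irf7 at least 24.5-fold higher (adjusted p = 1.29e-11). Macrophage genes rose in 9 of 12 cases (adjusted p = 1.76e-05, adjusted p = 0.381 with an estimated correlation), led by the lipopolysaccharide co-receptor Cd14 at 4.38 (SE 0.22). In the neutrophil list 7 of 10 rose (adjusted p = 0.00138, adjusted p = 0.381 with an estimated correlation), with S100a8 at least 38.6-fold (adjusted p = 8.89e-06) and the cytokine Il1b at least 15.6-fold higher (adjusted p = 1.78e-05). In the MHC class II list 6 of 7 rose (adjusted p = 0.00115, adjusted p = 0.381 with an estimated correlation). The fibroblast and matrix list had 10 of 14 members up (adjusted p = 0.000266, adjusted p = 0.381 with an estimated correlation, 12 adjusted over the list alone), with Col1a1 at 3.71 (SE 0.53). The mesenchymal program list had 7 of 13 up (adjusted p = 0.00674, adjusted p = 0.381 with an estimated correlation), with the matrix protein Tnc at least 11.7-fold higher (adjusted p = 1.08e-06). The endothelium list had 9 up and 1 down of 11 (adjusted p = 0.00674, adjusted p = 0.381 with an estimated correlation). Smooth muscle genes went the other way, with 7 of 11 lower (adjusted p = 0.00674, adjusted p = 0.423 with an estimated correlation, 8 adjusted over the list alone) and the muscle filament gene Des at -3.51 (SE 0.85). The other counts of immune and stromal lists were the same when adjusted over the list alone.

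Metabolic and cell cycle lists differed as well. Of 17 glycolysis and hypoxia genes 8 rose (adjusted p = 0.0016, adjusted p = 0.423 with an estimated correlation, 10 adjusted over the list alone), with the oxygen sensor Egln3 at least 17.6-fold higher (adjusted p = 2.85e-08). Mitosis genes rose in 8 of 15 cases (adjusted p = 0.0131, adjusted p = 0.563 with an estimated correlation). DNA replication genes rose in 8 and fell in 1 of 23 (adjusted p = 0.0479, adjusted p = 0.63 with an estimated correlation). The amino acid and ATF4 program had 10 of 17 members down and 3 up (adjusted p = 0.00674, adjusted p = 0.381 with an estimated correlation), with the asparagine synthetase Asns at -3.53 (SE 0.32) and Atf4 itself at -1.84 (SE 0.25). Lists that did not pass included ribosome biogenesis (0 up, 7 down of 17, adjusted p = 0.0959) and immediate early and heat shock (5 up, 2 down of 13, adjusted p = 0.0959). Oxidative phosphorylation (3 up, 8 down of 17, adjusted p = 0.148), B and plasma cell (3 up of 5, adjusted p = 0.148) and androgen response (3 up, 6 down of 13, adjusted p = 0.154) did not pass. Nor did sterol and fatty acid synthesis (7 up, 3 down of 18, adjusted p = 0.295), tubulins (1 up, 1 down of 15, adjusted p = 0.626) and blood (1 down of 2, adjusted p = 0.626). The same held for T and NK cell (2 up, 3 down of 10, adjusted p = 0.73), adipocyte (0 of 4 by limma, also 0 at an unadjusted p under 0.05, adjusted p = 0.817) and skeletal muscle (1 up, 1 down of 8, adjusted p = 0.817). FoxO-type genes (5 up, 6 down of 14, adjusted p = 0.972), seminal vesicle (0 of 9 by limma, 1 lower at an unadjusted p under 0.05, adjusted p = 0.972) and lysosome and autophagy (3 up, 5 down of 17, adjusted p = 0.991) did not pass either. The seminal vesicle list had a median of 0.74, a mean of -0.11 and a test pointing down. Adjusted over the list alone, immediate early genes counted 6 up, oxidative phosphorylation 4 up, T and NK cell genes 3 up, ribosome biogenesis 1 up and tubulins 0 down, and all other counts of this paragraph but glycolysis were the same.

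In all, 5829 genes differed between NPK tumours and wild type, 2868 higher and 2961 lower. Of 16 lists that passed, 1 call, proximal luminal, held with an estimated correlation between genes. For the other lists adjusted p was 0.381 to 0.63 with an estimated correlation. The DNA replication call ended without wild-type array 1 (adjusted p = 0.0821) or vehicle LONG array 2 (adjusted p = 0.102) or 3 (adjusted p = 0.0767). Genotype, strain and slide all differed between these groups.

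**Figure D1:**
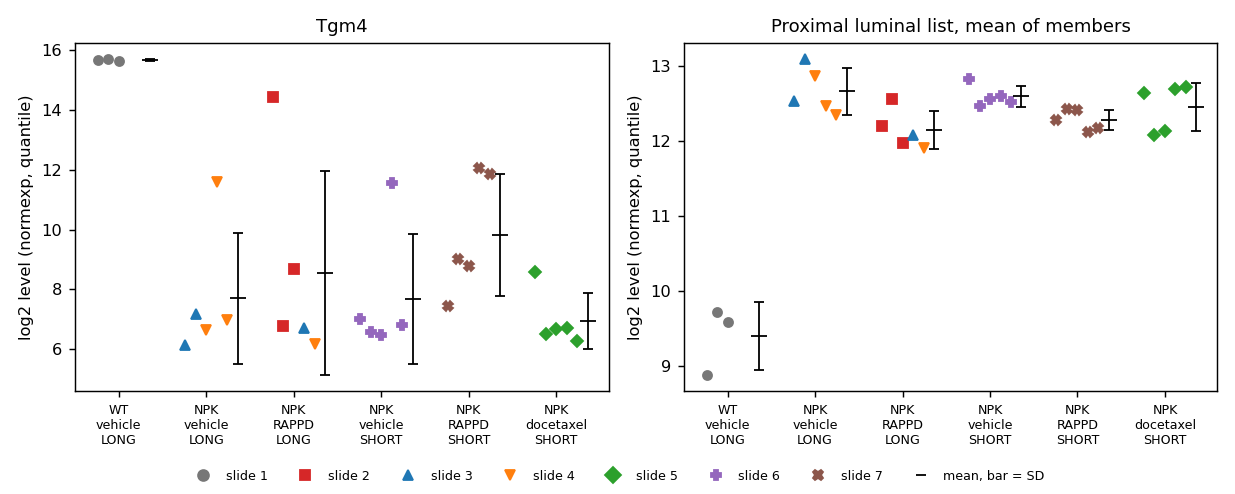
Log2 level of Tgm4 and mean log2 level of the proximal luminal list on each array (points, coloured by slide) in the 6 groups, with the group mean and SD as black bars. Tgm4 was lower in NPK tumours by 7.98 log2 units with vehicle LONG array 4 at 11.58, and 7 of 9 proximal luminal genes were higher.

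RAPPD was compared with vehicle in the SHORT arm (n = 5 each), which asks what the drug pair, read as a MEK and an mTOR inhibitor, changes in tumours. Direct readouts of ERK activity fell together. Dusp6, an ERK phosphatase induced by ERK itself, fell by 4.21 (SE 0.57, adjusted p = 1.25e-05) and Dusp4 fell by 3.14 (SE 0.34, adjusted p = 9.08e-07). The immediate early factor Egr1 fell by 3.12 (SE 0.45, adjusted p = 2.8e-05) and Ccnd1, which encodes cyclin D1, fell by 2.13 (SE 0.29, adjusted p = 1.1e-05). Etv5 was at least 2.56-fold lower (adjusted p = 8.26e-05), with no RAPPD array above background. In the MAPK/ERK output list 12 of 17 fell (adjusted p = 4.49e-11, adjusted p = 0.135 with an estimated correlation, 14 adjusted over the list alone). RAPPD SHORT arrays 4 and 5 stood apart from arrays 1 to 3 in some readouts. Dusp6 was at 10.08 and 10.36 against 7.11 to 7.97, Egr1 at 10.17 and 10.49 against 6.96 to 8.16. The list means were 8.81 and 8.95 against 8.11 to 8.22. Dusp4 (7.15 and 8.33 against 6.96 to 8.30) and Ccnd1 (12.14 and 11.98 against 11.60 to 12.02) lay close to the other arrays. On arrays 4 and 5 47.5% and 47.0% of probes were above background, against 42.0% to 43.0% on arrays 1 to 3. The noise that sets this threshold was lower there, at 12.65 and 11.76 against 15.42 to 16.39. Readouts that did not pass were Etv4 at -1.25 (SE 0.58, adjusted p = 0.128) and Spry4 at -0.61 (SE 0.28, adjusted p = 0.12). Nor did the topoisomerase Top2a at -1.44 (SE 0.61, adjusted p = 0.0917) and Cdkn1a at 0.01 (SE 0.25, adjusted p = 0.978).

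Growth programs were lower under RAPPD SHORT. DNA replication genes fell in 5 of 23 cases (adjusted p = 0.0012, adjusted p = 0.692 with an estimated correlation, 9 adjusted over the list alone), led by the replicative helicase subunit Mcm7 at -2.05 (SE 0.15) and Uhrf1 at -1.82 (SE 0.49). Mitosis genes fell in 3 of 15 cases (adjusted p = 0.0134, adjusted p = 0.692 with an estimated correlation), among them Cdc20 at -1.80 (SE 0.48). The mitosis list median was -0.82, and with the seminal vesicle list mean as a covariate it was -0.13 and the call ended (adjusted p = 0.373). Ribosome biogenesis genes fell in 5 of 17 cases (adjusted p = 0.00311, adjusted p = 0.257 with an estimated correlation, 7 adjusted over the list alone), with the RNA polymerase I subunit Polr1b at -1.22 (SE 0.22) and Bop1 at -1.35 (SE 0.27). FoxO-type genes, which are restrained by AKT signalling, rose in 4 of 14 cases (adjusted p = 0.0211, adjusted p = 0.239 with an estimated correlation, 5 adjusted over the list alone), with the ubiquitin ligase Fbxo32 at 1.07 (SE 0.24) and Pik3ip1 at 0.85 (SE 0.16). The androgen-responsive protease Tmprss2 rose by 0.98 (SE 0.18) and the luminal factor Foxa1 by 0.90 (SE 0.16). Krt8 fell by 1.28 (SE 0.15) and Krt7 fell by 1.01 (SE 0.16).

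Fibroblast and matrix genes fell in 3 of 14 cases under RAPPD SHORT (adjusted p = 0.0382, adjusted p = 0.692 with an estimated correlation, 5 adjusted over the list alone), with Col1a1 at -2.22 (SE 0.46) and fibronectin (Fn1) at -1.90 (SE 0.51). Seminal vesicle genes rose in 3 of 9 cases (adjusted p = 0.011, adjusted p = 0.692 with an estimated correlation, 5 adjusted over the list alone), among them the secretory proteins Svs3b at 5.85 (SE 1.17) and Svs2 at 4.19 (SE 1.51, adjusted p = 0.0476). The Svs2 call ended without vehicle SHORT array 1, 2, 4 or 5 or RAPPD SHORT array 2, 3, 4 or 5 (adjusted p = 0.0669 to 0.13). The list mean was 14.4 ± 0.444 (SD, n = 5) with RAPPD and 11.3 ± 2.44 (SD, n = 5) with vehicle. These genes also varied widely without drug. Vehicle SHORT array 3 had a list mean of 14.66, inside the RAPPD SHORT range of 13.70 to 14.79. On the wild-type arrays Svs2 was at 6.29, 14.67 and 14.20. The rise thus cannot be assigned to the drug. In all 2984 genes passed, 1508 higher and 1476 lower, of which 153 rose and 440 fell by at least 1 log2 unit. Other probes of the 2984 genes moved the same way in 61% (SE 1) of cases, beside 80% (SE 0.62) for NPK against wild type. Of these genes 119 had another probe called the opposite way, so some calls may reflect single probes. On the SHORT slides the arrays at positions D and E had skeletal muscle list means of 8.65 to 10.91 against 6.99 to 8.08 at positions A to C, and 1427 genes passed without them. The fibroblast call ended without vehicle SHORT array 4 (adjusted p = 0.0642) or 5 (adjusted p = 0.132), RAPPD SHORT array 1 (adjusted p = 0.0756) or positions D and E (adjusted p = 0.288). The seminal vesicle call ended without positions D and E (adjusted p = 0.197). With the closest pair of arrays in each NPK group averaged, the fibroblast call ended (adjusted p = 0.0854), as did 8 of the 54 calls of named genes, Svs2 among them (adjusted p = 0.153).

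**Figure D2:**
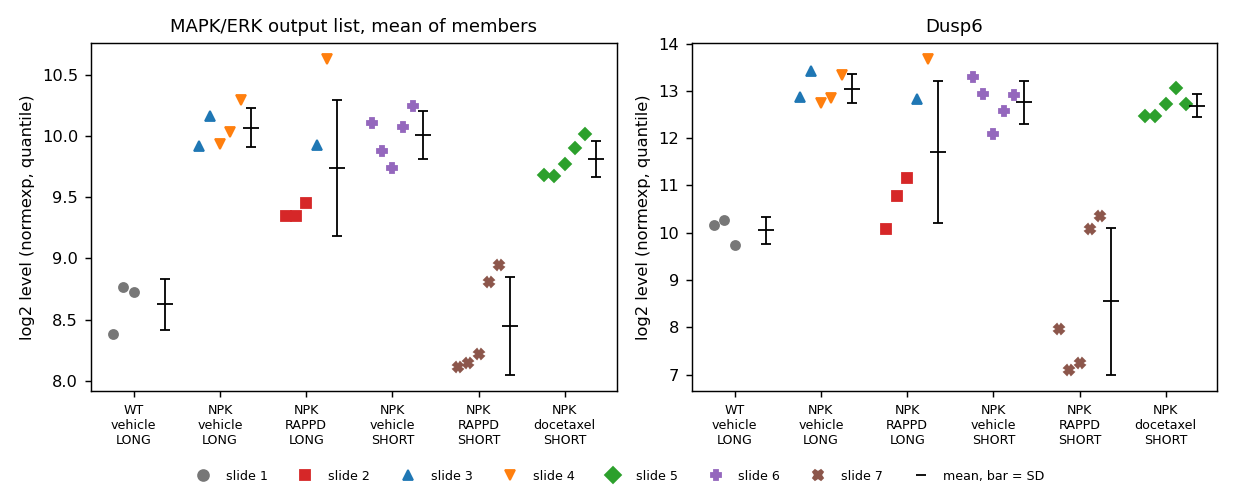
Mean log2 level of the MAPK/ERK output list and log2 level of Dusp6 on each array (points, coloured by slide) in the 6 groups, with the group mean and SD as black bars. List means were 8.11 to 8.95 with RAPPD SHORT and 9.74 to 10.25 with vehicle SHORT, and those of RAPPD LONG were 9.34 to 9.46 on slide 2, 9.93 on slide 3 and 10.64 on slide 4.

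RAPPD was compared with vehicle in the LONG arm (n = 5 each). Seminal vesicle genes rose in 6 of 9 cases (adjusted p = 3.25e-08, adjusted p = 0.406 with an estimated correlation, 9 adjusted over the list alone), with Svs3b at 5.61 (SE 1.17, adjusted p = 0.00629). Svs2 was at 5.60 (SE 1.51, adjusted p = 0.0255) and Svs3a at least 19.2-fold higher (adjusted p = 0.0225). Without drug Svs2 also varied, with levels of 6.29 to 14.67 on the wild-type arrays. The Svs2 call ended without RAPPD LONG array 1, 2 or 3 or vehicle LONG array 2, 3 or 4 (adjusted p = 0.0526 to 0.0874), and that of Svs3a without RAPPD LONG array 1 or 3 or vehicle LONG array 4 (adjusted p = 0.0509 to 0.0903). Endothelium genes fell in 5 of 11 cases (adjusted p = 1.38e-06, adjusted p = 0.406 with an estimated correlation, 8 adjusted over the list alone), with the sialomucin Emcn at -1.35 (SE 0.28), the junction protein Cdh5 at -1.13 (SE 0.25) and Pecam1 at -1.13 (SE 0.25). The macrophage mannose receptor Mrc1 fell by 2.30 (SE 0.28, adjusted p = 0.000115) and the chemokine Ccl5 rose by 2.54 (SE 0.47, adjusted p = 0.00301). The mucosal proteins Dmbt1 and Gp2 were lower, Dmbt1 at -4.98 (SE 0.77, adjusted p = 0.000644) and Gp2 by at least 6.37-fold (adjusted p = 0.00222). Sterol and fatty acid synthesis genes fell in 3 of 18 cases (adjusted p = 0.00741, adjusted p = 0.675 with an estimated correlation, 9 down and 1 up adjusted over the list alone), with Sqle at -1.74 (SE 0.42) and Dhcr7 at -1.34 (SE 0.22). The Sqle call ended without RAPPD LONG array 1, 2 or 3 (adjusted p = 0.0548 to 0.0658). The amino acid enzyme Asns rose by 1.36 (SE 0.28).

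ERK readouts did not pass in this arm. Dusp6 was at -1.34 (SE 0.57, adjusted p = 0.163), Egr1 at -1.11 (SE 0.45, adjusted p = 0.144) and Ccnd1 at -0.59 (SE 0.29, adjusted p = 0.226). Etv5 was at -0.53 (SE 0.29, adjusted p = 0.295), Etv4 at -0.55 (SE 0.58), Spry4 at 0.16 (SE 0.28), Top2a at -1.09 (SE 0.61) and Cdkn1a at -0.65 (SE 0.25). In the MAPK/ERK output list 1 of 17 fell, Phlda1 at -1.08 (SE 0.23, adjusted p = 0.00831), and the list did not pass (adjusted p = 0.204). The mitosis list passed as lower with 0 of 15 members called by limma, and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.0363, adjusted p = 0.815 with an estimated correlation, median -0.70). The smooth muscle list passed as higher with 0 of 11 called by limma, and 4 higher at an unadjusted p under 0.05 (adjusted p = 0.00248, adjusted p = 0.675 with an estimated correlation, 1 adjusted over the list alone). With the seminal vesicle list mean as a covariate, chosen after seeing the data, the smooth muscle list passed as lower (median -0.846, adjusted p = 0.00491). The mitosis list median was then 0.029 (adjusted p = 0.573).

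These values differed between slides. Against all vehicle LONG arrays, the 3 RAPPD arrays of slide 2 gave Dusp6 -2.37 (adjusted p = 0.00185), Ccnd1 -1.19 (adjusted p = 0.000597), Top2a -2.56 (adjusted p = 8.35e-06) and a MAPK/ERK list median of -0.82 (adjusted p = 0.0133). The other 2 RAPPD arrays gave Dusp6 0.21 (adjusted p = 0.936), Ccnd1 0.30 (adjusted p = 0.694), Top2a 1.11 and a list median of 0.28 (adjusted p = 0.183). The mitosis list median was -1.70 (adjusted p = 2.59e-10) from slide 2 and 0.86 (adjusted p = 2.66e-08) from the other arrays. With slide as a fixed block over slides 2 to 4, Svs3b was at 4.07 (adjusted p = 0.335), Mrc1 at -1.93 (adjusted p = 0.108), Emcn at -1.79 (adjusted p = 0.107) and Dusp6 at 0.23 (adjusted p = 0.794). Within slide 3 these genes were at 7.35, -1.57, -1.37 and -0.32, and within slide 4 at 1.15, -2.25, -2.17 and 0.71. Svs2 was at 6.32 within slide 3 but at -0.84 within slide 4, and at 2.53 with the block (adjusted p = 0.447). The fitted value of Svs3a was likewise -0.47 within slide 4, and its call ended with the block (adjusted p = 0.395). The endothelium list kept its call with the block (median -1.33, adjusted p = 9.2e-10), as did the seminal vesicle list (median 2.77, adjusted p = 0.000853). The sterol list was at 0.13 (adjusted p = 0.606), the smooth muscle list at -0.05 (adjusted p = 0.64), the mitosis list at 0.93 (adjusted p = 7.19e-07) and the DNA replication list at 0.61 (adjusted p = 6.47e-10). Of the 15 lists that passed with the block 12 had not passed without it, and they rest on 2 RAPPD arrays. Besides DNA replication, those higher were the ATF4 program (median 0.36, adjusted p = 0.000164), ribosome biogenesis (0.40, adjusted p = 3.03e-05), glycolysis and hypoxia (0.46, adjusted p = 0.00216), interferon response (0.48, adjusted p = 0.0385) and tubulins (0.25, adjusted p = 0.0223). Those lower were fibroblast and matrix (-1.05, adjusted p = 8.96e-05), macrophage (-0.65, adjusted p = 8.96e-05), MHC class II (-0.82, adjusted p = 0.00216), lysosome (-0.27, adjusted p = 0.0139), androgen response (-0.29, adjusted p = 0.014) and proximal luminal genes (-0.20, adjusted p = 0.0385). Of these 15 calls 0 held with an estimated correlation (adjusted p = 0.152 to 0.686).

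In the LONG arm 941 genes passed, 458 higher and 483 lower, and 1 gene passed with slide as a fixed block against 1994 at an unadjusted p under 0.05. It was the endothelial Cd93 at -1.63 (SE 0.163, adjusted p = 0.0438), named after its value was seen. Slide as a random block left 244 genes. With the closest pair of arrays in each NPK group averaged 119 genes passed, and 18 of the 32 calls of named genes ended, as did those of the sterol (adjusted p = 0.062) and mitosis lists (adjusted p = 0.158). Without RAPPD LONG array 1, 2 or 3 the count was 366, 441 or 324, without array 4 or 5 it was 1677 or 2002, and without vehicle LONG array 1 or 4 it was 625 or 483. The mitosis call ended without RAPPD LONG array 1 (adjusted p = 0.124), 2 (adjusted p = 0.25) or 3 (adjusted p = 0.184) and without vehicle LONG array 2 (adjusted p = 0.102) or 3 (adjusted p = 0.0849).

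**Figure D3:**
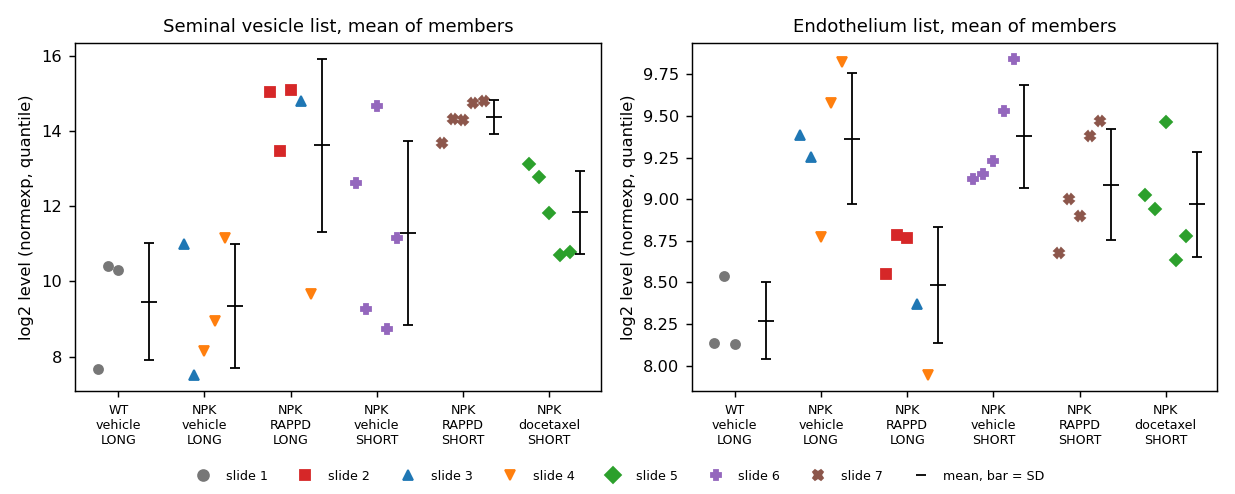
Mean log2 level of the seminal vesicle list and of the endothelium list on each array (points, coloured by slide) in the 6 groups, with the group mean and SD as black bars. Seminal vesicle means ranged from 9.66 to 15.10 with RAPPD LONG and from 7.51 to 11.16 with vehicle LONG, and 5 of 11 endothelium genes were lower with RAPPD LONG.

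The RAPPD effect differed between arms for 2554 genes, 1179 with a higher and 1375 with a lower value in LONG than in SHORT. Each SHORT group filled a slide alone, and vehicle arrays 4 and 5 resembled each other across arms. The LONG effect also averages unlike arrays. RAPPD LONG had MAPK/ERK list means of 9.34 to 9.46 on slide 2 but 9.93 and 10.64 on arrays 4 and 5, beside 9.92 to 10.30 with vehicle LONG. These differences therefore cannot be assigned to the arm. In the MAPK/ERK output list 9 of 17 genes had a higher value in LONG (adjusted p = 1.46e-05, adjusted p = 0.526 with an estimated correlation, 10 adjusted over the list alone), with Dusp4 at 3.66 (SE 0.48, adjusted p = 1.57e-05), Dusp6 at 2.87 (SE 0.80, adjusted p = 0.0135) and Ccnd1 at 1.54 (SE 0.40, adjusted p = 0.00891). Ribosome biogenesis genes did so in 3 of 17 cases, Bop1, Polr1b and Ddx21 (adjusted p = 0.00706, adjusted p = 0.526 with an estimated correlation). Tmprss2 differed by -1.86 (SE 0.26, adjusted p = 3.28e-05), Atf4 by 2.05 (SE 0.30, adjusted p = 6.81e-05) and Mrc1 by -1.43 (SE 0.40, adjusted p = 0.0138). Of the genes called in each arm, 83 changed the same way in both (23 higher, 60 lower, where independent lists give 49.99 and 51.6) and 192 the opposite way (102). Across genes, which are not independent replicates, the effects correlated at r = 0.0791 (jackknife SE 0.095) and rho = -0.0413. The r was 0.0444, 0.0511 or 0.143 without vehicle SHORT array 4, 2 or 3 and 0.0483 without RAPPD LONG array 4. It was 0.0411 without background correction and 0.0248 with the LONG effect taken from slides 3 and 4 with slide as a fixed block. With slide as a random block 924 genes differed, and 1486 did with the closest pair of arrays in each NPK group averaged, where the call of Mrc1 ended (adjusted p = 0.0564). The number was 2122 without vehicle LONG arrays 4 and 5 and 2014 without vehicle SHORT arrays 4 and 5, and the ribosome biogenesis call ended without RAPPD LONG array 5 (adjusted p = 0.0727).

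Docetaxel was compared with vehicle in the SHORT arm (n = 5 each), a cytotoxic drug set beside the targeted pair. Fibroblast and matrix genes were lower as a list (adjusted p = 4.93e-07, adjusted p = 0.587 with an estimated correlation), with 8 of 14 lower when adjusted over the list alone. Adjusted over all genes 1 passed, the collagen Col1a1 at -1.94 (SE 0.46, adjusted p = 0.0245), a call that ended without docetaxel array 2, 4 or 5 or vehicle SHORT array 4 or 5 (adjusted p = 0.0609 to 0.0708). The p53 targets Aen, an exonuclease, and Bbc3, a pro-apoptotic BCL2 family member, rose by 0.78 (SE 0.15, adjusted p = 0.00943) and 0.92 (SE 0.20, adjusted p = 0.0173), and the Bbc3 call ended without docetaxel array 5 (adjusted p = 0.0502). The p53 list did not pass (2 of 19, adjusted p = 0.0626). The beta-tubulin Tubb5 rose by 0.93 (SE 0.19, adjusted p = 0.0114), 1 of 15 in the tubulin list, which did not pass (adjusted p = 0.519). Paip1 rose by 1.33 (SE 0.31), a call that ended without docetaxel array 4 or 5 or vehicle SHORT array 4 or 5 (adjusted p = 0.0614 to 0.0698). S100a13 fell by 1.72 (SE 0.35). ERK readouts did not pass, with Dusp6 at -0.07 (SE 0.57, adjusted p = 0.969), Egr1 at -0.40 (SE 0.45), Ccnd1 at 0.19 (SE 0.29), Top2a at 0.14 (SE 0.61) and Cdkn1a at 0.44 (SE 0.25, adjusted p = 0.4).

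The endothelium list passed as lower under docetaxel with 0 of 11 members called by limma, and 5 lower and 1 higher at an unadjusted p under 0.05 (adjusted p = 0.0144, adjusted p = 0.872 with an estimated correlation). The immediate early and heat shock list passed as lower (adjusted p = 0.0495, adjusted p = 0.587 with an estimated correlation, 4 down and 1 up adjusted over the list alone). Of its 13 genes 1 fell, the phosphatase Dusp1 at -1.17 (SE 0.29, adjusted p = 0.0321), a call that ended without docetaxel array 2, 4 or 5 or vehicle SHORT array 1, 2, 4 or 5 (adjusted p = 0.0534 to 0.0849). In all 352 genes passed, 199 higher and 153 lower, 29 of them by at least 1 log2 unit. The count was 203, 125, 175 or 168 without docetaxel array 1, 2, 4 or 5, and 222, 232, 233, 157 or 146 without vehicle SHORT array 1 to 5. It was 31 without positions D and E. In that setting the fibroblast (adjusted p = 0.232) and endothelium lists did not pass. The MHC class II list passed there as higher (median 0.76, adjusted p = 0.0457). The count was 35 with the closest pair of arrays in each NPK group averaged, where 22 of the 24 calls of named genes and those of the immediate early (adjusted p = 0.0888) and endothelium lists (adjusted p = 0.113) ended. The immediate early call ended without docetaxel array 4 (adjusted p = 0.101) or 5 (adjusted p = 0.0733) or vehicle SHORT array 1 (adjusted p = 0.198). The endothelium call ended without docetaxel array 4 (adjusted p = 0.101) or 5 (adjusted p = 0.0652) or vehicle SHORT array 5 (adjusted p = 0.0629).

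RAPPD SHORT was set directly against docetaxel SHORT (n = 5 each). With RAPPD the MAPK/ERK output list was lower, with 10 of 17 members down (adjusted p = 2.82e-13, adjusted p = 0.0524 with an estimated correlation, 12 adjusted over the list alone), Dusp6 at -4.14 (SE 0.57, adjusted p = 0.00012) and Ccnd1 at -2.33 (SE 0.29, adjusted p = 5.14e-05). DNA replication genes were lower in 6 of 23 cases (adjusted p = 6.9e-08, adjusted p = 0.343 with an estimated correlation, 10 adjusted over the list alone), with Mcm7 at -1.63 (SE 0.15). Mitosis genes were lower in 3 of 15 cases (adjusted p = 6.72e-05, adjusted p = 0.448 with an estimated correlation, 10 adjusted over the list alone). Ribosome biogenesis genes were lower in 3 of 17 (adjusted p = 4.57e-05, adjusted p = 0.0652 with an estimated correlation, 7 adjusted over the list alone). Tubulins were lower in 5 of 15 cases (adjusted p = 0.000216, adjusted p = 0.343 with an estimated correlation, 8 adjusted over the list alone), with Tubb6 at -1.80 (SE 0.33) and Tuba1b at -0.85 (SE 0.17). The smooth muscle list was higher (adjusted p = 1.93e-05, adjusted p = 0.423 with an estimated correlation, 8 adjusted over the list alone). Of its 11 genes 1 passed over all genes, the contractile Cnn1, at least 1.91-fold higher (adjusted p = 0.0014).

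FoxO-type genes were higher with RAPPD than with docetaxel in 1 of 14 cases, Bcl6 at 0.66 (SE 0.19), and as a list (adjusted p = 0.00145, adjusted p = 0.0524 with an estimated correlation, 7 adjusted over the list alone). Seminal vesicle genes were higher in 2 of 9 cases (adjusted p = 0.00145, adjusted p = 0.448 with an estimated correlation, 4 adjusted over the list alone), Svs3b at 4.12 (SE 1.17) and Sva at 3.95 (SE 1.20). Each of these 3 calls ended without docetaxel array 4 or 5 or RAPPD SHORT array 2, 3 or 4 (adjusted p = 0.0556 to 0.11). The Svs3b and Sva calls ended without RAPPD SHORT array 5 (adjusted p = 0.0606 and 0.0915), the Svs3b and Bcl6 calls without docetaxel array 1 (adjusted p = 0.0767 and 0.0871) or 2 (adjusted p = 0.0811 and 0.0556), and the Sva and Bcl6 calls without docetaxel array 3 (adjusted p = 0.106 and 0.0829). Basal genes were lower in 2 of 10 cases (adjusted p = 0.0291, adjusted p = 0.448 with an estimated correlation), Itgb4 at -0.85 (SE 0.14) and Krt17 at -1.37 (SE 0.28). In all 871 genes differed, 297 higher and 574 lower with RAPPD. The count was 539 or 536 without docetaxel array 4 or 5 and 299 without positions D and E, where the seminal vesicle and basal calls (adjusted p = 0.124 each) and the smooth muscle call (adjusted p = 0.0965) ended. With the closest pair of arrays in each NPK group averaged 306 genes differed, and 23 of the 46 calls of named genes ended. The basal call ended too without docetaxel array 3 (adjusted p = 0.0598) or RAPPD SHORT array 4 (adjusted p = 0.11) or 5 (adjusted p = 0.0909).

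**Figure D4:**
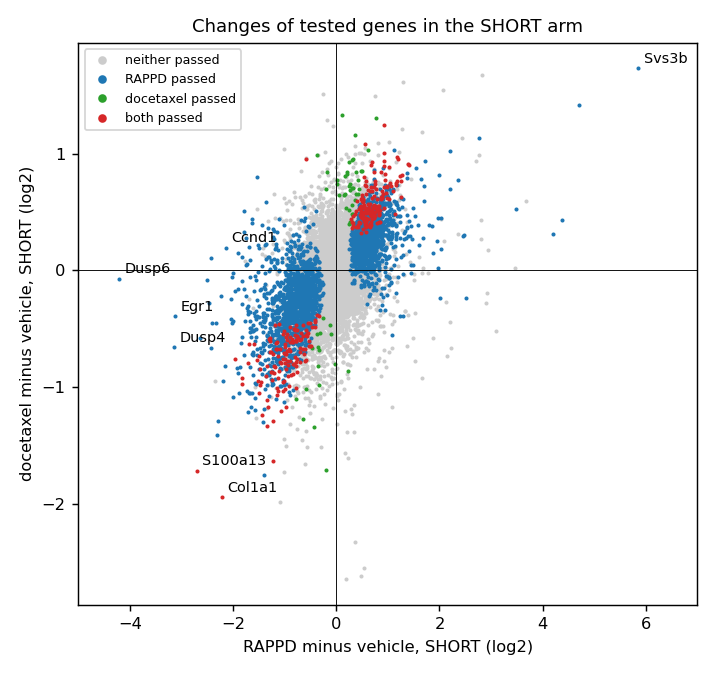
Each point is a gene, with its log2 change under RAPPD SHORT against vehicle on 1 axis and under docetaxel SHORT against the same vehicle arrays on the other, coloured by which comparison it passed. Dusp6, Dusp4 and Egr1 lie far to the RAPPD side, and Col1a1 and S100a13 are lower under both.

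Calls under RAPPD SHORT and docetaxel overlapped in 294 genes changed the same way (158 higher, 136 lower, where independent lists give 21.7 and 16.3) and 1 the opposite way. Both use the same vehicle arrays. Unchanged groups simulated against those arrays shared 0 calls of limma. Groups without any change yield few calls after adjustment, so this count sets no yardstick for the overlap. Across genes, which are not independent replicates, the correlation of the simulated groups was 0.499 beside the observed r = 0.548 and rho = 0.574. The observed covariance was 0.0964 beside 0.0341 simulated. With the vehicle arrays split between the comparisons, a median of 31 genes (2 to 126) was shared where independent lists give 2.73, with a median r of 0.312 and covariance of 0.0645. The overlap was 166, 101, 145 or 141 without docetaxel array 1, 2, 4 or 5, and 180, 192, 129 or 119 without vehicle SHORT array 1, 2, 4 or 5. It was 454 without RAPPD LONG array 5, which enters through the shared estimate of spread.

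Genes that separate NPK tumours from wild type were followed under treatment. Across these 5829 genes the tumour difference correlated with the RAPPD SHORT effect at r = -0.0928 (rho = -0.0273), and 48.7% moved against the tumour direction. For docetaxel it was r = 0.138 (rho = 0.168) and 43.3%. For RAPPD LONG it was r = -0.605 (rho = -0.623) and 76.2%, but both sides share the vehicle LONG arrays, and simulated unchanged groups gave r = -0.568 and 73.8%. The simulation held no tumour difference, so its r cannot say how much of the observed r comes from the shared arrays. Over all genes the covariance was -0.261 beside -0.0342 simulated, and with the vehicle arrays split its median was -0.231 (-0.269 to -0.166). Over the tumour genes called in each split the median r was -0.541 (-0.627 to -0.341). Of 711 genes called in both, 678 went the opposite way, where independent lists give 198. With the vehicle arrays split, a median of 154 (8 to 357) did so, where independent lists give 37.4. Simulated unchanged groups gave 0, but groups without any change yield few calls after adjustment, so that count is no yardstick. In the sample titles, slide numbers of wild type and of the slide 2 RAPPD arrays differ only in their last digits. Those of vehicle LONG differ earlier. A difference between such sets of slides would enter both comparisons with opposite signs. Splitting the vehicle arrays cannot remove it, so the reversal cannot be assigned to the drug. Without vehicle SHORT array 1, 2 or 3 the RAPPD SHORT value was -0.0474, -0.0477 or -0.171, and without background correction it was -0.305 (jackknife SE 0.105).

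Vehicle SHORT and vehicle LONG tumours (n = 5 each) were compared to see how far the arms differ without drug. The arms share no slide, so a difference between slides cannot be told apart from one between arms. Arrays 4 and 5 of LONG resembled arrays 4 and 5 of SHORT, so the groups may not be independent. The seminal vesicle list passed as higher in SHORT with 0 of 9 members called by limma, and 1 higher at an unadjusted p under 0.05 (adjusted p = 0.00405, adjusted p = 0.987 with an estimated correlation, median 1.93), and the other 30 lists did not pass. The p53 target Eda2r was at least 1.31-fold lower in SHORT (adjusted p = 0.0145), a call that ended without vehicle SHORT array 3 or 4 (adjusted p = 0.0532 and 0.0502). The epithelial adhesion gene Epcam passed as higher (adjusted p = 0.0488), but it was above background on 0 vehicle LONG and 2 of 5 vehicle SHORT arrays and no fold can be given. Its call ended without vehicle LONG array 2, 3, 4 or 5 or vehicle SHORT array 1, 2, 3 or 5 (adjusted p = 0.0749 to 0.157). Among the genes lower in SHORT were the kinase Bmx (at least 2.82-fold, adjusted p = 1.24e-05) and the keratin Krt80 (at least 1.42-fold, adjusted p = 1.86e-06). Neither was above background on any of the 5 vehicle SHORT arrays. In all 246 genes passed, 46 higher and 200 lower, 23 did so with slide as a random block, and 125 did with the closest pair of arrays in each NPK group averaged. The count was 141, 158 or 163 without vehicle LONG array 2, 4 or 5 and 146 without vehicle SHORT array 3. The seminal vesicle call ended without vehicle LONG array 2 (adjusted p = 0.0822) or vehicle SHORT array 1 (adjusted p = 0.0689) or 3 (adjusted p = 0.196).

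In each comparison 2 to 5 of the 31 lists had a median, mean and test that differed in sign, and 0 of these lists passed camera.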

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

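The tests of the RAPPD LONG arrays and of the genes shared by docetaxel and RAPPD SHORT were chosen only after the result was seen, as were the one on 500 variable genes and the splits with arrays averaged, and the other tests of vehicle arrays 4 and 5 were set before their results were seen.

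Arrays standing apart from the other 4 of their group were found in 23 of 353 groups of values tested. Chance flags about 1 in 20 groups. RAPPD LONG array 5 stood apart in 5 of them, with a glycolysis and hypoxia list mean of 12.78 (others 11.06 to 11.48), tubulins at 9.94 (9.35 to 9.52), T and NK cell at 8.268 (8.99 to 9.11), Spry4 at 9.136 (7.09 to 7.29) and Svs2 at 6.667 (14.11 to 15.37). Vehicle SHORT array 3 had an amino acid and ATF4 list mean of 10.25 (9.72 to 9.78), FoxO-type genes at 9.545, p53 targets at 9.292 (9.73 to 9.85) and Sval2 at 9.013. Docetaxel array 2 had a glycolysis and hypoxia mean of 11.22 (11.38 to 11.40). RAPPD SHORT array 1 was lowest for adipocyte genes at 7.573, Svs3b at 15.32, Svs2 at 12.51 and Ambp at 8.315, and RAPPD SHORT array 4 was at 6.131 for Inhba and 7.546 for Cdkn3. In vehicle LONG, Tgm4 was at 11.58 on array 4 (others 6.13 to 7.17), Sva at 8.663 on array 1, Col10a1 at 6.958 on array 3 and Pdap1 at 10.3 on array 2. Otol1 was at 8.206 on vehicle SHORT array 1 and 9.668 on docetaxel array 1, and Mmp13 at 13.1 on docetaxel array 3.

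The RAPPD effect differed between arms, by limma's test of the difference, for 2554 genes, and 525 was the most that any of 99 other splits called. LONG minus SHORT, the largest positive differences by fitted value were Adap1 4.71, Ptpre 4.41, Ccl5 3.70, Dusp4 3.66, Mmp12 3.05, S100a13 2.96, Ccdc6 2.94 and Dusp6 2.87. The largest negative ones by fitted value were Reg1 -5.58, Dmbt1 -5.35, Reg3b -5.32, Gp2 -5.10, Sult1c2 -4.79, Olfm4 -4.45, Wfdc12 -3.85 and Cdhr5 -3.79. Gp2 was above background on no RAPPD LONG array, so the size and rank of its difference are not measured. Among ERK readouts Egr1 differed by 2.01 and Ccnd1 by 1.54. Etv5 was at 1.26 by fitted value, but it was above background on no RAPPD SHORT array, so the size of its difference is not measured. The median difference was 1.24 in the MAPK/ERK output list and 0.38 in the ribosome biogenesis list. The LONG effect behind these values differed between slides, so they cannot be assigned to the arm.

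Probes without a single gene symbol also passed, 1370 for NPK against wild type, 283 for RAPPD LONG, 716 for RAPPD SHORT, 93 for docetaxel, 296 for RAPPD against docetaxel, 243 between the vehicle arms and 645 for the difference between RAPPD arms.

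The first pattern is that the RAPPD LONG difference was carried by the 3 arrays of slide 2, which called 3263 genes against 46 from the other 2 arrays. In the MAPK/ERK list the lowest vehicle LONG array was 0.462 above the highest slide 2 RAPPD array. That argues against labels swapped between RAPPD and vehicle only if the low values of slide 2 come from the drug. With no vehicle array on slide 2 this is not shown, so swapped labels stay open. A difference of slide 2 acting on single probes is a candidate explanation for some of these genes, as 67.3% (SE 0.94) of their other probes moved the same way beside 75.8% (SE 0.86) for tumour genes matched on size. Whether the RAPPD arrays of slides 3 and 4 lack a drug response stays open, as the lower of the 2 was 0.014 above the lowest vehicle LONG array in the MAPK/ERK list, which only restates the pattern, while their endothelium list means of 8.37 and 7.94 lay below all vehicle LONG arrays (8.77 to 9.82). A difference in tissue or drug exposure between slides stays open, as slide 2 held no vehicle array and seminal vesicle list means ranged from 9.66 to 15.10 over RAPPD LONG arrays.

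The second pattern is that vehicle LONG arrays 4 and 5 resembled vehicle SHORT arrays 4 and 5. RNA of the same tissue on both arrays of a pair is a candidate explanation, which the tests below do not settle. Values picked after they were seen matched within pairs. Tgm4 was at 11.578 and 11.545 on array 4 of LONG and SHORT. Fibroblast list means were 12.03 and 12.04 on array 4 of LONG and SHORT, and 12.58 and 12.60 on array 5. The comparison of vehicle arms, the difference between RAPPD arms and the correlation of RAPPD effects take these arrays as separate. These arrays lay lowest of all on principal component 4, at -43.5 to -29.7. Over 6908 genes with little weight on it, the lower pair differed by -0.092 from the highest other of 325 pairs across groups. There 19 other pairs reached the lower pair. That bound was too strict, as it sets 1 pair against the highest of many (SD 0.0695 over the others). Over the 500 genes most variable in the other NPK groups the pairs correlated at 0.919 and 0.893, the crossed pairs at 0.544 and 0.549 and the rest at up to 0.416. Tissue content common to all these arrays as the whole cause is argued against. Over the 6908 genes the pairs correlated on average 0.191 above the crossed pairs. Nerve content was not measured, and content shared only within a pair stays open. No biological explanation other than tissue content was tested.

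The third pattern is 294 genes that moved alike under docetaxel and RAPPD SHORT. Chance values of the shared vehicle arrays stay open. The median docetaxel shift was 0.613 against vehicle SHORT and 0.432 against vehicle LONG, so a smaller shift remained with the other vehicle group. This cannot decide the question, as the genes were picked for passing in these same docetaxel arrays. Vehicle LONG is also no independent control, as some of its arrays resembled vehicle SHORT arrays. A RAPPD response present in both arms is argued against by a mean shift of -0.13 in RAPPD LONG. A difference between slides acting on single probes is a candidate explanation for some of these genes, as 57.9% (SE 3.1) of their other probes moved the same way beside 78.2% (SE 2.8) for tumour genes matched on size. A response to both drugs stays open for genes whose other probes do move. In the sample titles, the slide numbers of docetaxel and RAPPD SHORT differ only in their last digits, while that of vehicle SHORT differs earlier. A difference between such sets of slides would move both treatments alike and stays open too. Against vehicle LONG these genes, picked for this pattern, shifted by 0.486 in docetaxel and 0.665 in RAPPD SHORT. The other groups lay at -0.174 to 0.

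Other splits of the same arrays were also tested with limma. For NPK against wild type 1 of 56 splits, the real split with 5829 genes, called as many, and the highest other called 2011, with vehicle LONG arrays 1 to 3 set apart. For RAPPD LONG, RAPPD SHORT, docetaxel, RAPPD against docetaxel and the difference between arms it was 1 of 100 each, with 816, 1085, 9, 69 and 525 genes as the highest other beside the real 941, 2984, 352, 871 and 2554. The 816 of RAPPD LONG came with RAPPD array 5 in the place of vehicle array 3, both of slide 4. Between the vehicle arms it was 3 of 100. The highest of these called 611, more than the real 246, and set LONG arrays 1 to 3 with SHORT arrays 1 and 2 apart from the rest, which points to a structure of the arrays other than the arm. With slide as a random block 23 genes passed there. These splits take arrays as independent, which the labels do not state. Some arrays of a group were close, as docetaxel arrays 4 and 5 (r = 0.985 across genes, next pair 0.966) and RAPPD LONG arrays 2 and 3 (0.985, next 0.981), and wild-type arrays 2 and 3 reached 0.986. With the closest pair of each NPK group averaged, 1 of 35 splits called as many genes for NPK against wild type (5581, highest other 3307), RAPPD SHORT (2077, 173), docetaxel (35, 6) and RAPPD against docetaxel (306, 10). For these 4 counts the real split thus called the most genes, and 1 of 35 is the smallest share possible. That share cannot exclude chance over 7 comparisons, and it takes the averaged arrays as independent. Nor can it exclude a difference between slides. For RAPPD LONG 2 of 35 called as many genes, the highest other calling 226 beside 119, so there the real split did not call the most. Between the vehicle arms it was 1 of 35 (125, 5) and for the difference between arms 1 of 100 (1486, 706), but independence stays open for vehicle arrays 4 and 5 across arms, which both use.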

How the results depend on the processing

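Leaving out positions D and E, leaving out vehicle arrays 4 and 5, array position as a block, the seminal vesicle covariate, the closest pair of arrays in each NPK group averaged and an estimated correlation with slide as a block were chosen after seeing the data. Over 56 settings the cause of a change was not tested, except where fewer arrays or a threshold on size lowers a count by construction. The labels give no replicate numbers, so arrays were not paired. With array position (A to C against D and E) as a block, counts were 3177 for RAPPD SHORT, 422 for docetaxel and 1029 for RAPPD against docetaxel, and all 7, 3 and 9 list calls held. Signal over background limits genes near the floor, as 33.1% to 47.5% of probes were above it.

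With a log2 change of at least 1 required, counts were 3231 for NPK against wild type, 336 for RAPPD LONG, 593 for RAPPD SHORT, 29 for docetaxel, 230 for RAPPD against docetaxel, 33 between vehicle arms and 1191 for the difference between arms. For RAPPD LONG (941) the count was 556 without background correction, 94 from its own groups only, 4610 with array weights, 244 with slide as a random block, 46 without slide 2, 3263 from slide 2 only, 386 without vehicle arrays 4 and 5, 119 with pairs averaged and 79 with the covariate. It was 1 with slide fixed over slides 2 to 4 (Cd93) and 1 over slides 3 and 4 (Gad2), named after their values were seen, against 1994 and 1404 at an unadjusted p under 0.05. Fits within slide 3 or within slide 4 rest on 1 RAPPD array each, so their counts are not given. RAPPD SHORT (2984) had 1427 without positions D and E. Docetaxel (352) had 540 with the deposited log2 values, 169 with the mean of probes, 1024 with array weights, 31 without positions D and E, 35 with pairs averaged and 89 without vehicle arrays 4 and 5. RAPPD against docetaxel (871) had 520 from its own groups only, 299 without positions D and E, 306 with pairs averaged and 396 with the covariate. Vehicle arms (246) had 158 without background correction, 140 with median scaling, 150 with loess, 136 with the deposited log2 values, 64 with the stricter filter, 147 from its own groups only, 23 with slide as a random block, 125 with pairs averaged and 117 without vehicle LONG arrays 4 and 5. The difference between arms (2554) had 4325 with array weights, 1486 with pairs averaged and 924 with slide as a random block. The tumour signature correlation under RAPPD SHORT was -0.3047 without background correction, and the overlap of RAPPD SHORT and docetaxel was 448 with the deposited log2 values and 137 with the mean of probes.

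Without 1 array, counts were 4820 to 5621 for NPK against wild type, 324 to 2002 for RAPPD LONG, 2499 to 3028 for RAPPD SHORT, 125 to 357 for docetaxel, 536 to 1066 for RAPPD against docetaxel, 141 to 182 between vehicle arms and 2029 to 3166 for the difference. The lowest and highest for RAPPD LONG came without RAPPD arrays 3 and 5, and the other arrays behind a change over 1.5 times stand with each comparison. The correlation of RAPPD effects was 0.0444 to 0.1434, the signature correlation -0.1705 to -0.0474 and the overlap 101 to 454.

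Directions reversed for RAPPD LONG mainly with slide. With either fixed slide block Hpgd was at -0.05, and the sterol, mitosis and DNA replication lists at 0.134, 0.932 and 0.61. Without slide 2 these lists were at 0.121, 0.86 and 0.609. Within slide 3 Atf4 was at -0.22. Within slide 4 Svs2 was at -0.839, Ceacam10 -0.538, Spink8 -0.224, Svs3a -0.465, Spink11 -0.596, Top2a 2.139, Sqle 0.335, Cdk1 1.985 and Hpgd -0.843. With the covariate Svs1 was at -0.063, Spink11 at -0.025, the mitosis list at 0.029 and the smooth muscle list at -0.846, where it passed as lower (adjusted p = 0.00491). The seminal vesicle list was then at -0.486 in RAPPD SHORT and -0.334 against docetaxel, as removing that list by construction does. With the mean of probes Trp53inp1 differed by 0.043 between arms, and without positions D and E the MHC class II list was at 0.76 under docetaxel.

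Of named genes that passed, 62 of 70 kept their call for NPK against wild type under the alternatives that keep all arrays of the comparison, 4 of 32 for RAPPD LONG, 31 of 54 for RAPPD SHORT, 4 of 24 for docetaxel, 13 of 46 for RAPPD against docetaxel, 6 of 18 between vehicle arms and 21 of 46 for the difference. Fits within slides or with slide fixed rest on 1 or 2 RAPPD LONG arrays, so a call lost there says nothing about stability. The share of higher calls moved from 48.7% to 37.1% without background correction and 58.9% with loess in RAPPD LONG. It moved from 50.5% to 62.4% in RAPPD SHORT and from 56.5% to 81.9% in docetaxel with median scaling, and from 34.1% to 46.8% with loess and 44.5% with the deposited log2 values in RAPPD against docetaxel. Median scaling moved the median of all genes in the difference between arms to -0.118. List calls ended for DNA replication in NPK against wild type (adjusted p = 0.0593 to 0.172 over 4 settings), mitosis there without background correction (0.143), mitosis in RAPPD LONG (0.0531 to 0.173 over 5), sterol genes there without vehicle arrays 4 and 5 (0.0619), with pairs averaged (0.062) and with the covariate (0.178), mitosis in RAPPD SHORT with the covariate (0.373), seminal vesicle genes there without vehicle arrays 4 and 5 (0.089), mitosis and FoxO-type genes in RAPPD SHORT with the stricter filter (0.0508 each), fibroblast genes there (0.0671 to 0.288 over 6), immediate early genes under docetaxel (0.0525 to 0.0943 over 7), endothelium there without positions D and E (0.726) or vehicle arrays 4 and 5 (0.186) or with pairs averaged (0.113), smooth muscle in RAPPD against docetaxel with the covariate (0.0546) and ribosome biogenesis in the difference between arms without background correction (0.0739). By fry, which tests the direction of a list without setting it against other genes, all 16 list calls held for NPK against wild type and both for the difference between arms. The 3 of docetaxel ended (0.103, 0.103 and 0.42), as did mitosis and smooth muscle in RAPPD LONG (0.323 and 0.179). So did mitosis, fibroblast and seminal vesicle genes in RAPPD SHORT (0.158, 0.158 and 0.0574), mitosis, basal and seminal vesicle genes in RAPPD against docetaxel (0.0934, 0.0908 and 0.103) and the 1 call between vehicle arms (0.928). Called genes with another probe called the opposite way numbered 108, 5, 119, 3, 1, 1 and 95 in the order of comparisons above.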

Other observations

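The shares of other probes and the comparison of vehicle arrays 1 to 3 were tests chosen after seeing the results, and the genes below came from the rule and lists fixed before.

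Under RAPPD SHORT the AP-1 factor Jun rose by 1.65 (SE 0.25, adjusted p = 4.74e-05) while its partner Fos fell by 1.04 (SE 0.20, adjusted p = 0.000421). The antiproliferative gene Btg2 was at least 1.85-fold higher (adjusted p = 6.4e-05), and the growth arrest gene Gadd45a fell by 1.20 (SE 0.22, adjusted p = 0.000417). The beta-tubulin Tubb6 fell by 2.05 (SE 0.33, adjusted p = 7.74e-05) and the stress keratin Krt17 fell by 1.39 (SE 0.28, adjusted p = 0.000708). These 6 genes kept their calls without each array in turn and under all other alternatives run. Cox6c, a subunit of cytochrome oxidase, was lower under RAPPD SHORT at -1.13 (SE 0.17, adjusted p = 3.39e-05). It was also lower under docetaxel at -1.03 (SE 0.17, adjusted p = 0.00151), against the same vehicle arrays, and at -1.11 without positions D and E (adjusted p = 0.0516).

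Other probes of called genes moved the same way in 80.0% (SE 0.62) of cases for NPK against wild type, 76.9% (SE 1.6) for RAPPD LONG and 61.0% (SE 1.0) for RAPPD SHORT. For docetaxel it was 59.5% (SE 2.9), for RAPPD against docetaxel 71.7% (SE 1.8), between the vehicle arms 58.0% (SE 4.7) and for the difference between RAPPD arms 61.2% (SE 1.1). Among genes changed by at least 1 log2 unit it was 85.3%, 76.9%, 72.7%, 73.7%, 85.1%, 43.8% and 68.3% in the same order. Between the vehicle arms, 49 genes passed from arrays 1 to 3 of each arm alone, and 41 of them differed the same way in both arrays 4 and 5. Their median level was 6.81 log2 units against 8.46 for all genes. Turned to the called direction and set against the vehicle LONG mean, these genes averaged 0.8 to 1.07 on SHORT arrays of every treatment. On LONG arrays, wild type included, they averaged -0.11 to 0.16. They followed arm or slide whatever the treatment, and arm and slide cannot be told apart here.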
